A study of Mus musculus with 6 samples.

How the data were processed

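The series measured messenger RNA in 6 cultures of mouse pluripotent cells, with 1 sequencing library per culture. Embryonic stem cells (ESC) with a Cre-deleted H2A.X gene were set beside their Flox/Flox counterpart, in which the gene is flanked by recombination sites. Induced pluripotent stem cells (iPSC) derived from peritoneal fibroblasts (PF) or tail tip fibroblasts (TTF) were labelled 4N+ or 4N-, with 1 line of each label from each parental cell type. The labels give only 4N+ and 4N-. These were read, from knowledge outside the labels, as the outcome of tetraploid complementation, the test of whether a line can form a whole embryo in a tetraploid host blastocyst. All cultures were at passage 25 and, per the labels' protocols, grew on feeder cells with LIF, were moved to gelatin-coated plates to remove the feeders, and were lysed in Trizol for total RNA and Illumina TruSeq mRNA libraries.

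The authors deposited 3 tables, each comparing 2 libraries over the same 22558 gene names. Reads passed through CASAVA and TopHat2 on the mm9 genome, per the submitters' processing notes. The quantifying program, its settings, the annotation and all versions are not given in the sources used here, and strand use is not stated. Each table has the column layout of a gene-level comparison of 2 conditions: per the file headers it holds a value per library, a p-value, a q-value and a significance call made by the authors. The library values were treated as FPKM (fragments scaled to transcript length and library depth) as deposited by the authors, because they were never negative, were not whole and summed to between 263928 and 356260 per library. The deposited log2 fold change and its test statistic (units other than expression) were checked against the FPKM columns and enter no result. Ratios were recomputed because infinite values had been replaced by a very large number. Spreadsheet handling had turned 25 gene names into dates, and 87 entries carried more than 1 name. The tables were presumably scaled separately, so ratios were formed within a table, and levels set side by side across tables carry that limit. The iPSC fits with no replicate block or with a library left out also compare values across tables and carry it too.

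Read totals are not among the values used here. Effective depth was recovered from 1132 intronless olfactory and vomeronasal receptor genes, whose lowest values are worth 1 fragment. The divisor that made their values whole was 39058900 fragments for the knockout ESC, 49856900 for the Flox/Flox ESC, 44388600 and 44389400 for the 4N- and 4N+ PF lines, and 61180300 and 59154500 for the 4N- and 4N+ TTF lines. With it, 100% of the 31 to 117 receptor values tested per library came within 0.05 of a whole number. The divisor had been fitted to the 1-fragment values among them, such as 19 of the 31 in the 4N+ PF line and 73 of the 117 in the knockout ESC. For those values the match is no check. The divisor is an effective one, not the number of mapped reads. At that depth 1 FPKM on a transcript of 2000 bp stood for 70.2 to 110 fragments. Lengths of spliced genes could not be recovered in this way, so no count test was run. Intervals on fragment numbers are exact Poisson or conditional binomial intervals at the 95% level and cover counting error only.

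Values were analysed as log2(FPKM + 1). Fold changes on this scale understate the change of genes with low expression. A gene was counted as measured in a comparison when it reached 1 FPKM in at least 1 of its libraries. With 1 library per condition, a comparison has no replicate check, and genes differing at least 2-fold on the log2(FPKM + 1) scale were counted with no p-value. The 4 iPSC libraries were fitted with limma 3.58.1 in R 4.3.3 (trend, moderated test, Benjamini-Hochberg adjusted p below 0.05) with parental cells as a block, which equals a test on the 2 within-table ratios. This leaves 1 residual degree of freedom per gene, and nothing in the labels says that 2 lines from 1 parental cell type came from the same animal. Simulated data had the 4N- against 4N+ design over 11843 genes. On them the fit recovered 18% of 50 genes changed 1.5-fold, 94% of 50 changed 2-fold and 100% of 50 changed 4-fold. It called 0.112% of 11643 unchanged genes. Whether the real genes vary as the simulated ones did was not tested, so these shares describe the simulated data only. They do not measure how reliable the calls on the real libraries are. Those calls numbered 0 with no expression filter and 93 without small RNA genes.

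A set of 17 gene lists was fixed before the data were examined, with 411 members, of which 8 (Tfcp2l1, Tfap2c, Tfap2a, Syna, Map2, Pramef25, Tmem92 and Spi1) are not analysed here. No gene belonged to more than 1 list. For each comparison, the median log2 ratio of the measured members was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. Such a percentile describes these libraries and is not a test of the condition. A list was said to stand outside the random lists below the 2.5 or above the 97.5 percentile. On the H2A.X comparison over 12086 genes, 6% of 200 random lists of 20 genes fell outside that range, and 89.5% did after 0.5 was added to their log2 ratios. In the iPSC fit, lists were tested with camera at a preset correlation of 0.01, and with an estimated correlation and with fry as alternatives. Camera sets the genes of a list against the other genes, whereas fry asks whether they changed at all. An interferon response list was added after the data had been seen.

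The rule for named genes was also fixed beforehand. It took H2afx in every library, the 8 genes with the largest increase and the 8 with the largest decrease in the ESC comparison among genes at 5 FPKM or more, the 8 genes in each direction with the largest smaller-of-both-pairs ratio in the iPSC, and up to 4 members of each list per comparison. Clone names, small RNA genes and entries with several names were left out of the top genes. All members of the pluripotency, trophoblast and imprinted lists could be named, and Xist and Y-linked genes were given in every library. Chromosome medians were taken over measured genes minus the median of all autosomal genes, and a chromosome was said to stand apart when it lay beyond the range of the other autosomes by more than their median absolute deviation. Adding 0.3 to the chromosome 5 ratios of the TTF pair, over 11334 genes, moved that chromosome's median by 0.29.

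Alternatives were other pseudocounts (0.1 and 0.5), no expression filter, a minimum of 5 FPKM, ratios centred on the median of genes at 5 FPKM or more in both libraries, 1.5-fold and 3-fold limits, the iPSC fit with no replicate block, without trend and with robust moderation, and each iPSC library or pair left out. Left out after the data had been seen were small RNA genes (723 entries), chromosomes 6, 8, 11 and 17, and genes whose status in the authors' tables was not OK. Positions are those of the deposited tables on mm9, written 1-based. GC content and transcript length came from the GENCODE M21 transcripts, matched by name for 97.8% of genes, without use of its coordinates. Near-identical copies were sought with blastn 2.17.0 among the same transcripts: 65 of 243 genes searched matched another gene at 95% identity over 200 bp or more. How the authors treated reads that fit several places is not stated. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.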

Results

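Gene expression was measured by mRNA sequencing in 6 mouse pluripotent cell cultures, 1 library each: H2A.X Cre knockout and Flox/Flox ESC, 4N- and 4N+ iPSC from peritoneal fibroblasts, and 4N- and 4N+ iPSC from tail tip fibroblasts. H2A.X is the histone H2A variant that is phosphorylated around DNA double-strand breaks. Effective depth was 39058900 to 61180300 fragments, and between 11031 and 11852 genes reached 1 FPKM in a library. No condition has a second library within its table, so none of the 2-library comparisons has a replicate check.

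H2afx (chromosome 9, 44142798 to 44144156 on mm9), which encodes H2A.X, stood at 6.18 FPKM in the knockout ESC and 34.9 FPKM in the Flox/Flox ESC. The knockout value was 5.65-fold lower and amounted to 17.7% of the Flox/Flox value (conditional exact binomial 95% interval 15.6% to 20.1%, from 279 and 2011 fragments, counting error only). The direction was that of the labels, and transcript remained in the library labelled knockout. In the iPSC lines H2afx stood at 75.2 FPKM (4N-) and 69.1 FPKM (4N+) in the peritoneal fibroblast pair, and at 65.3 FPKM (4N-) and 70.9 FPKM (4N+) in the tail tip fibroblast pair. The gene has 1 near-identical partner among annotated transcripts, so its value is uncertain to that extent.

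The first comparison asked what differs in ESC labelled as H2A.X knockout. Gene-level values cannot tell whether the remaining H2afx fragments came from undeleted cells or from a part of the gene left after deletion. Genes of the trophoblast lineage, which forms the placenta, were far higher in the knockout, and genes of the pluripotency network were moderately lower. Of 23 measured trophoblast genes, 18 were at least 2-fold higher in the knockout and none was 2-fold lower. The list median was 2.10 on the log2 scale and lay above the matched random lists (percentile 100). In the Flox/Flox library 17 trophoblast members reached 1 FPKM, so the others measured entered through the knockout. With no filter the median was 1.74 over 27 genes (percentile 100). Several trophoblast genes were among the largest increases of the genes ranked, those at 5 FPKM or more without clone names, small RNA genes and entries with several names. They were the simple epithelial keratins Krt18 (659 against 26.7 FPKM) and Krt8 (188 against 6.80 FPKM) and the galectin gene Lgals3 (97.2 against 3.02 FPKM). The X-linked placental homeobox gene Rhox6 (247 FPKM, 22.4-fold higher) and the trophoblast giant cell factor Hand1 (34.0 against 0.829 FPKM) were also among them. Gata2 (5.54 against 0.284 FPKM) and Gata3 (1.64 against 0.133 FPKM) were also higher. Cdx2, an early trophectoderm factor, stayed below 1 FPKM in both libraries, and Eomes was listed at 1.79 against 2.65 FPKM. Krt8 has a near-identical copy and is uncertain to that extent.

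Of 26 measured pluripotency genes, 25 were lower in the knockout, 8 of them at least 2-fold, and the list median of -0.84 lay below all 10000 random lists. The 5-methylcytosine oxidase gene Tet1 stood at 21.5 against 82.1 FPKM, L1td1 at 94.3 against 313 FPKM, Sox2 at 48.5 against 142 FPKM and Jarid2 at 31.5 against 84.8 FPKM. The core factor gene Pou5f1 differed less (166 against 265 FPKM), and Nanog was level at 111 FPKM in both libraries, with a log2 ratio of -0.00 that became 0.20 after centring. The median of genes at 5 FPKM or more in both libraries was itself shifted by -0.20, and after centring on it the pluripotency median was -0.64 and the trophoblast median 2.30.

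Other lineage and stress groups were higher in the knockout. Of 12 measured extraembryonic endoderm genes, 6 were at least 2-fold higher (median 0.91, percentile 100, but 0.36 over 30 genes with no filter and 2.02 over 7 genes at a minimum of 5 FPKM), led by the basement membrane collagens Col4a2 (29.3 against 1.77 FPKM) and Col4a1 (45.0 against 3.33 FPKM). The fibroblast list, with 10 of 14 genes at least 2-fold higher (median 1.15, percentile 100, but 0.68 over 25 genes with no filter), was led by Cyr61 (116 against 7.98 FPKM), Tagln (62.3 against 7.36 FPKM) and Thbs1 (10.7 against 0.849 FPKM). In the Flox/Flox library 8 extraembryonic endoderm and 9 fibroblast members reached 1 FPKM, so the others measured entered through the knockout. The 3 fibroblast genes named encode secreted or cytoskeletal proteins, while fibrillar collagen Col1a1 stood at only 0.291 FPKM in the knockout. Of 24 p53 target genes, 6 were at least 2-fold higher (median 0.53, percentile 100), among them Plk2 (32.0 against 8.56 FPKM), Btg2 (39.4 against 11.3 FPKM) and Cdkn1a (50.8 FPKM, 2.67-fold higher), the cyclin-dependent kinase inhibitor p21. Of 18 immediate early and stress genes, 8 were at least 2-fold higher (median 0.57, percentile 99.99, and 0.24 at a minimum of 5 FPKM), including Atf3 (11.3 against 1.31 FPKM) and Ddit3 (62.1 against 14.8 FPKM). Of 24 imprinted genes, 7 were at least 2-fold higher (median 0.38, percentile 99.95, but 0.11 at percentile 84.0 with no filter, and 0.58 after centring), with Igf2 at 426 against 14.7 FPKM, H19 at 13.9 against 1.44 FPKM and the growth inhibitor gene Cdkn1c at 36.6 against 6.44 FPKM. Airn (5.72 against 0.428 FPKM) overlaps Igf2r on the other strand, and since strand use is not stated its value is uncertain.

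All 22 analysed members of the 2-cell-like list, genes that mark rare ESC resembling the 2-cell embryo, were under 1 FPKM in the Flox/Flox library. The 7 that reached 1 FPKM in the knockout had a median of 1.45 (percentile 99.99), a direction fixed by that filter, and with no filter the median of 21 members was 0.62 (percentile 100), all 21 being higher. Tcstv1 stood at 10.9 against 0.564 FPKM and Zscan4d at 1.69 against 0.135 FPKM, both from families of near-identical copies. Among 21 germline genes 3 were at least 2-fold higher (median 0.47, percentile 98.9, but 0.21 at percentile 93.7 at a minimum of 5 FPKM), led by Taf7l (16.9 against 2.31 FPKM). The macrophage list, with 5 measured genes, had a median of 1.76 (percentile 100) through Csf1r (11.3 against 0.131 FPKM), Cd74 and Cd68, but with no filter its median was 0.07 at percentile 68.0.

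Genes of DNA repair and its signalling were lower in the knockout in 29 of 29 cases, 4 of them at least 2-fold (median -0.65, percentile 0, and -0.45 after centring). Xrcc5, which encodes the Ku80 end-joining protein, stood at 37.1 against 89.2 FPKM, Nbn at 5.05 against 11.8 FPKM and Chek1 at 15.1 against 32.7 FPKM. Cell cycle genes had a median of -0.57 (percentile 1.42, and 3.13 at a minimum of 5 FPKM) that became -0.36 after centring, with Mycn at 20.3 against 55.9 FPKM, whereas the inhibitors Cdkn2a (10.1 against 2.74 FPKM) and Cdkn2b (4.33 against 1.28 FPKM) were higher. Histone variant and chromatin genes (median -0.46, percentile 4.92, and -0.25 after centring), reference genes (median -0.18, percentile 88.0, and 0.03 after centring), neural ectoderm genes (median 0.11, percentile 47.9) and mesoderm genes (median 0.39, percentile 67.2) lay within the random lists. At a minimum of 5 FPKM the neural ectoderm median turned to -1.17 over 6 genes, outside the random lists (percentile 0), and the mesoderm median to -0.13 over 3 genes. The 9 measured neural ectoderm genes divided into 5 higher (1 at least 2-fold) and 4 lower (3 at least 2-fold). Neural regulators Otx2 (4.78 against 19.5 FPKM) and Gbx2 (2.02 against 8.81 FPKM) and the DNA methyltransferases Dnmt3a (13.3 against 35.8 FPKM) and Dnmt3b (36.0 against 89.4 FPKM) were lower in the knockout.

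Across 12086 measured genes, 905 were at least 2-fold higher and 449 at least 2-fold lower in the knockout, a higher share of 66.8%. After centring the numbers were 1412 and 202, a share of 87.5%. The largest increase among named genes was that of Cryab, a small heat shock protein gene (139 against 1.96 FPKM), followed by Igf2, Lgals3, Krt8, Krt18, Rhox6, Hand1 and the transglutaminase gene Tgm2 (38.7 against 1.07 FPKM). The largest decreases were those of Gpx2 (3.06 against 23.0 FPKM), Nlrp4f (1.99 against 15.6 FPKM), H2afx, Psma3 (2.86 against 17.8 FPKM), Enpp2 (1.20 against 9.47 FPKM), Spna1 (2.88 against 15.1 FPKM), Zfp459 (3.53 against 15.8 FPKM) and Enpp3 (13.6 against 53.4 FPKM). Psma3 has 4 near-identical partners, Zfp459 has 2, and Cryab, Igf2, Tgm2 and Gpx2 have 1 each. The authors' deposited table called 210 genes in this comparison, 202 higher and 8 lower in the knockout.

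**Figure D1:**
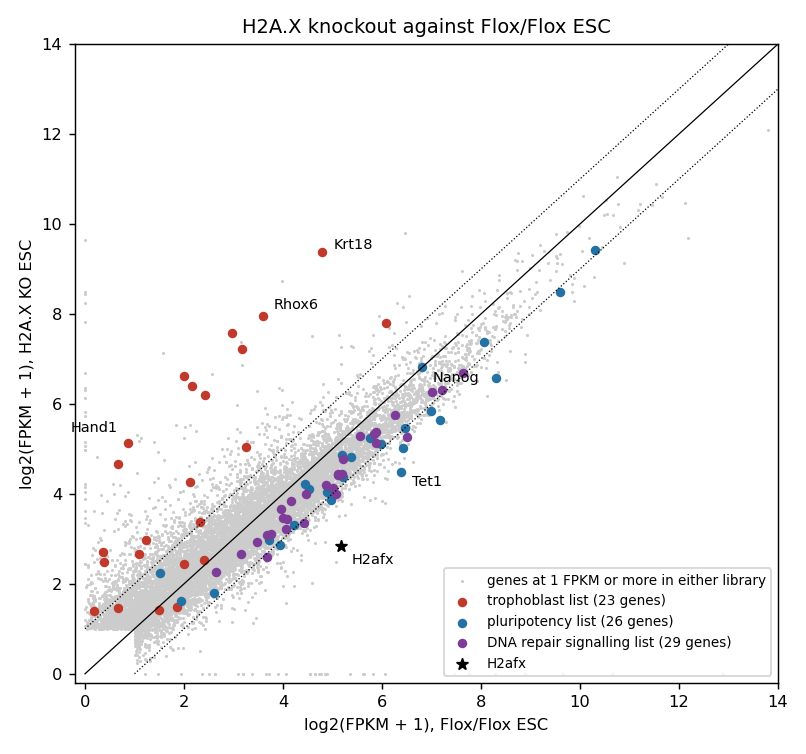
Each point is a gene at 1 FPKM or more in either library, with log2(FPKM + 1) in the Flox/Flox ESC on the horizontal axis and in the H2A.X knockout ESC on the vertical axis; the solid line marks equal values and the dotted lines 2-fold. Of the 23 trophoblast genes 18 lie on or above the upper dotted line, while 25 of 26 pluripotency genes and 29 of 29 DNA repair genes lie below the solid line.

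The second question was how iPSC labelled 4N- differ from those labelled 4N+. In the peritoneal fibroblast pair the long noncoding RNAs of the imprinted Dlk1-Dio3 region were near 0 in the 4N- line and abundant in the 4N+ line, and fibroblast genes were lower in the 4N- line. Of 21 fibroblast genes measured, 20 were lower, 10 of them at least 2-fold (median -0.70, percentile 0). All 21 reached 1 FPKM in the 4N+ line, so the filter let genes in through that line and favoured lower ratios. S100a4, Col1a2, Acta2 and Ccl2, each under 1 FPKM in the 4N- line, entered only in this way. S100a4 stood at 0.153 FPKM in the 4N- line and 40.1 FPKM in the 4N+ line, Col1a2 at 0.0228 and 5.41 FPKM, Acta2 at 0.872 and 6.29 FPKM and Ccl2 was listed at 0 in the 4N- line and at 2.62 FPKM in the 4N+ line. In the 2 ESC libraries and the tail tip fibroblast pair Col1a2 was at most 0.150 FPKM.

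Genes of the p53 list were higher in the 4N- line of this pair in 16 of 23 cases, none of them 2-fold (median 0.14, percentile 100, and 0.31 after centring), with Plk2 at 12.2 against 6.67 FPKM, Perp at 18.9 against 10.8 FPKM and Cdkn1a at 24.2 against 16.0 FPKM. Cdkn1a lies on chromosome 17, whose genes were shifted upward in this pair (median 0.37 above all autosomal genes). The 3 measured 2-cell-like genes, 2 of them at 1 FPKM in the 4N+ line, were higher (median 0.73, percentile 99.97, but 0.24 over 21 genes with no filter). Germline genes had a median of 0.15 (percentile 99.9, with 0.05 at a minimum of 5 FPKM and 0.32 after centring), with Mael at 11.2 FPKM, 1.49-fold higher. Pluripotency genes had a median of -0.08 (percentile 98.3) against a shift of -0.17 for genes at 5 FPKM or more in both libraries, and 0.09 after centring, so the sign depends on the scaling. None of the 26 differed 2-fold, and the largest ratios were those of Fbxo15 (55.2 against 32.9 FPKM), Tbx3 (1.76-fold higher than 5.67 FPKM), L1td1 (97.4 against 157 FPKM) and Sox2 (85.7 against 119 FPKM).

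The other 11 lists with at least 3 measured genes lay within the random lists in this pair at 1 FPKM. Trophoblast genes had a median of 0.01 (percentile 84.8) and extraembryonic endoderm genes of 0.06 (percentile 96.3). Medians were -0.22 for neural ectoderm genes (percentile 8.76), -0.22 for mesoderm genes (percentile 19.6), -0.07 for imprinted genes (percentile 83.9), -0.15 for DNA repair genes (percentile 69.3), -0.25 for histone and chromatin genes (percentile 11.4), 0.12 for macrophage genes (percentile 92.3), -0.28 for cell cycle genes (percentile 3.62), -0.18 for stress genes (percentile 27.8) and -0.20 for reference genes (percentile 48.1). Centring raised every median of this pair by 0.17, so that those of DNA repair and imprinted genes turned to 0.01 and 0.10. At a minimum of 5 FPKM neural ectoderm (-0.59, percentile 0.600, 4 genes), mesoderm (-0.81, 3 genes), macrophage (0.44, percentile 99.4, 3 genes) and extraembryonic endoderm genes (0.07, percentile 98.1) lay outside the random lists. With no filter the neural ectoderm median turned to 0.07 (percentile 99.1). In total 67 genes were at least 2-fold higher and 113 at least 2-fold lower in the 4N- line among 11606 measured, a higher share of 37.2% that became 51.1% after centring. Small RNA genes, which mRNA libraries capture poorly, made up 72 of these 180 genes. The authors' deposited table called 13 genes higher and 62 lower in the 4N- line.

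In the tail tip fibroblast pair the same noncoding RNAs were lower in the 4N- line, 2-cell-like and trophoblast genes were slightly higher, and Y-linked genes differed. All 15 measured 2-cell-like genes were higher in the 4N- line (median 0.54, percentile 100), none 2-fold, with Zscan4d at 8.53 against 3.78 FPKM, Zscan4c at 3.58 against 1.79 FPKM and Arg2 at 4.28 against 1.77 FPKM. Trophoblast genes had a median of 0.33 (percentile 100, and 0.15 over 29 genes with no filter), with 11 of 18 higher and none 2-fold, including Sct (5.45 against 3.07 FPKM), Rhox6 (17.1 against 10.6 FPKM) and Esx1 (3.03 against 1.67 FPKM). The Y-linked genes Eif2s3y (25.3 against 2.46 FPKM), Ddx3y (6.79 against 1.36 FPKM) and Uty (13.5-fold higher than 0.148 FPKM) were higher in the 4N- line, giving the sex chromosome list a median of 1.56 (percentile 100, 4 genes), and Kdm5d was at most 0.0403 FPKM in every library. In the other 4 libraries Eif2s3y, Ddx3y and Uty stayed below 1 FPKM, and Xist, the RNA that silences an X chromosome, was at most 0.975 FPKM in all 6 libraries.

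Extraembryonic endoderm genes of this pair had a median of 0.12 (percentile 99.3), with Srgn at 7.64 against 4.38 FPKM and Dab2 at 4.31 against 2.45 FPKM. At a minimum of 5 FPKM this median became -0.09. Fibroblast genes had a median of -0.12 (percentile 1.71) that became 0.01 with no filter. Medians of the remaining lists lay within the random lists at 1 FPKM: 0.01 for pluripotency (percentile 14.0), 0.01 for neural ectoderm (percentile 63.1), -0.10 for mesoderm (percentile 11.5), -0.00 for imprinted genes (percentile 52.7), 0.03 for p53 targets (percentile 68.7), -0.03 for DNA repair (percentile 9.92), 0.01 for histone and chromatin genes (percentile 30.2), 0.08 for germline (percentile 97.3), -0.00 for macrophage genes (percentile 52.6), 0.07 for the cell cycle (percentile 80.0), 0.04 for stress genes (percentile 78.6) and 0.02 for reference genes (percentile 26.5). With no filter the neural ectoderm median was 0.06 (percentile 99.3), and with a pseudocount of 0.1 the germline median was 0.11 (percentile 99.2). Among 11354 measured genes, 21 were at least 2-fold higher and 64 at least 2-fold lower in the 4N- line, and 67 of these 85 were small RNA genes. The authors' deposited table called 17 genes higher and 26 lower.

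**Figure D2:**
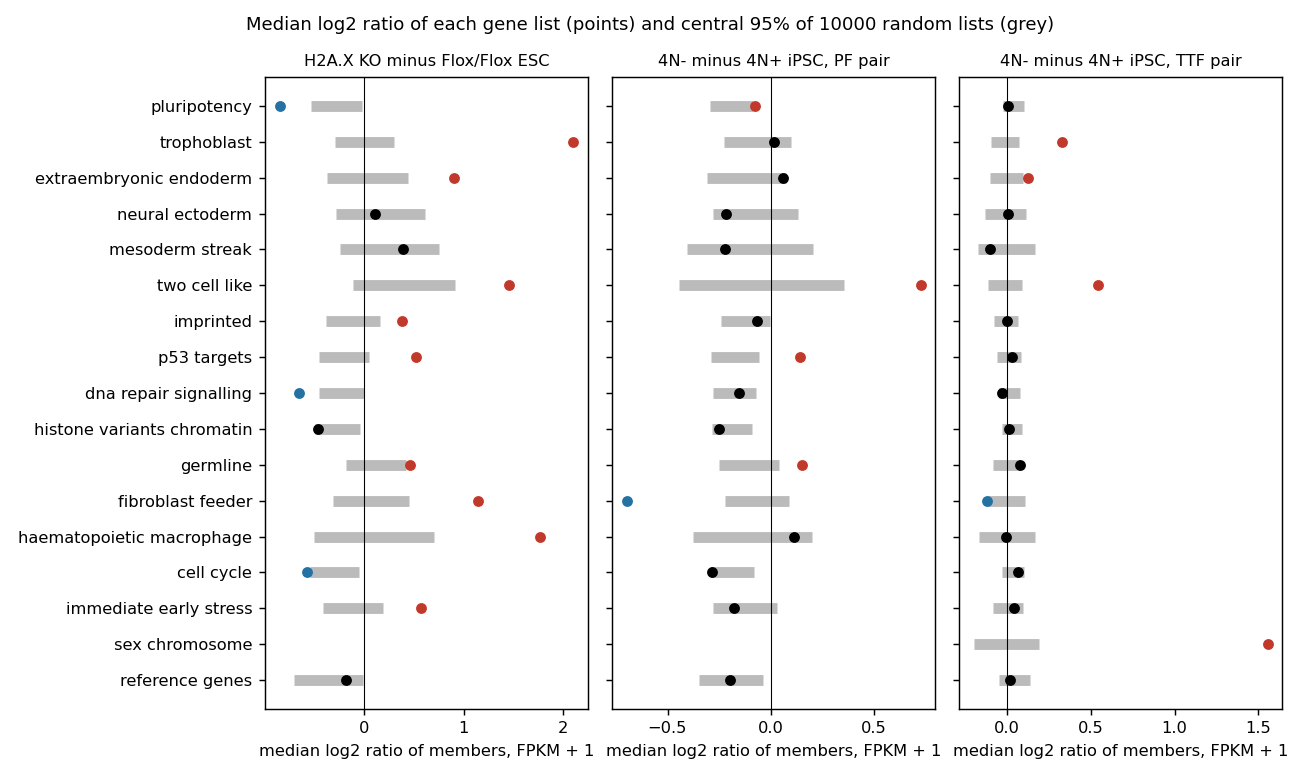
Points give the median log2 ratio, on the log2(FPKM + 1) scale, of the measured members of each gene list in the 3 comparisons, and grey bars give the central 95% of 10000 expression-matched random lists. Red points lie above and blue points below that range: 12 lists in the ESC, 5 in the peritoneal fibroblast pair and 5 in the tail tip fibroblast pair.

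Across both iPSC pairs, the imprinted noncoding RNAs Meg3, Rian and Mirg, expressed from the maternal chromosome 12, fell in the 4N- lines. Meg3 (110779206 to 110809939 on mm9) stood at 0.188 FPKM (4N-) and 44.1 FPKM (4N+) in the peritoneal pair and at 1.52 and 28.0 FPKM in the tail tip pair. Rian (110842155 to 110899921) stood at 0.200 and 58.1 FPKM and at 2.31 and 39.5 FPKM, and Mirg (110973191 to 110987667) at 0.0411 and 8.64 FPKM and at 0.493 and 8.51 FPKM. Both ESC libraries were at most 0.349 FPKM for all 3. The paternally expressed neighbours Dlk1 and Rtl1 were at most 0.544 FPKM in every library. In limma the mean log2 ratios were -4.39 for Meg3 (SE 0.30, Benjamini-Hochberg adjusted p = 4.41e-05), -4.62 for Rian (SE 0.34, adjusted p = 7.68e-05) and -2.94 for Mirg (SE 0.17, adjusted p = 1.28e-05), lower in 2 of 2 pairs. The calls ended in limma with no replicate block (adjusted p = 0.142, 0.208 and 0.142) and with no expression filter (0.978, 0.978 and 0.536), at the same log2 ratios, and with robust moderation for Meg3 and Rian (0.999 each). Without the block and with a library left out, limma's adjusted p for Meg3 was 0.635 without the 4N+ peritoneal line, 0.359 without the 4N+ tail tip line, 0.130 without the 4N- peritoneal line and 0.0222 without the 4N- tail tip line. The authors' deposited tables called all 3 in both pairs.

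**Figure D3:**
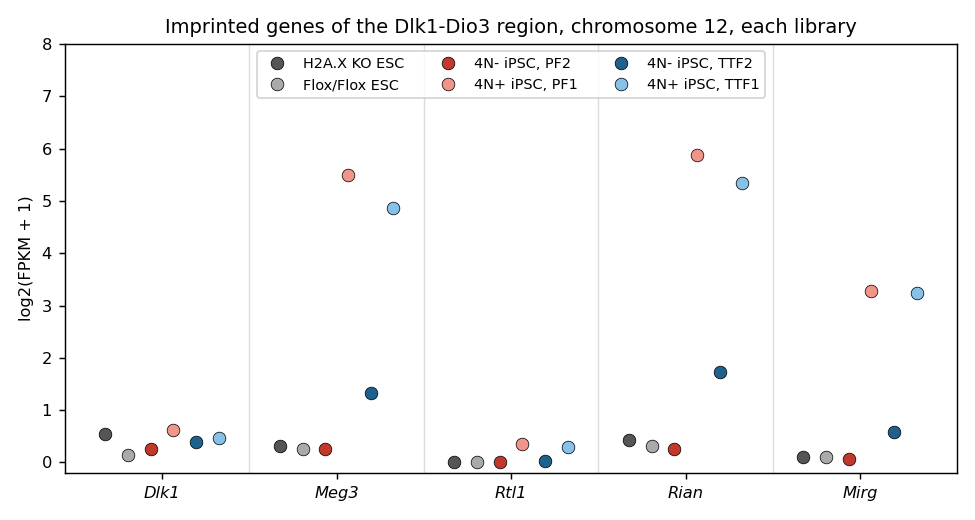
Each point gives log2(FPKM + 1) of 1 library for 5 imprinted genes of chromosome 12. The 4N+ iPSC lines lie at 44.1 and 28.0 FPKM for Meg3, above the 4N- lines at 0.188 and 1.52 FPKM and both ESC libraries, and Dlk1 and Rtl1 lie below 1 FPKM in all 6.

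In limma 446 of 11985 genes had an unadjusted p under 0.05, fewer than the 0.05 share that no difference at all would give. After Benjamini-Hochberg adjustment limma called 14 genes, 5 higher and 9 lower in the 4N- lines. Besides Meg3, Rian and Mirg these were 8 small RNA genes, the ribosomal protein gene Rps10 (log2 1.13, SE 0.17, adjusted p = 0.0383), the proteasome subunit gene Psma3 (0.96, SE 0.15, adjusted p = 0.0468) and Rangrf (2.03, SE 0.18, adjusted p = 0.000412 after Benjamini-Hochberg adjustment in limma). Rangrf, whose limma call ended with no replicate block and with no expression filter, was named after its values were seen. It was listed at 0.00249 to 0.00340 FPKM in both 4N+ lines and the knockout ESC, less than 1 fragment on a 2000 bp transcript (0.00910 to 0.0143 FPKM), and at 2.75 to 3.49 FPKM in the other 3 libraries. Rps10, Psma3 and Rangrf have 3, 4 and 3 near-identical partners, and Rps10 lies on chromosome 17, whose genes were shifted upward in the peritoneal pair. In limma the calls of Rps10 and Psma3 ended with a pseudocount of 0.5 (adjusted p = 0.0878 each), after centring (0.0506 and 0.0552), without trend (0.0960 and 0.177), with no filter (0.978 each), and with no replicate block or any library left out (1 each). The number of calls moved from 0 with no expression filter (602 at unadjusted p under 0.05) to 93 without small RNA genes, and was 1 without the 4N- peritoneal line and 3 without the 4N+ tail tip line. Psma3, higher in both 4N- lines, was lower in the knockout ESC.

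Among the other named genes with the same direction in both pairs, Spink3 (13.1 against 5.99 and 15.4 against 8.61 FPKM), Peg3, Tcstv1, Tcstv3, Mcts2 and Aqp3 were higher in the 4N- lines. Ldhb (67.3 against 164 and 35.9 against 63.5 FPKM), Trh (25.5 against 116 and 185 against 305 FPKM), Inpp5d (16.0 against 25.0 and 4.40 against 15.4 FPKM), Tnnt1, Emp1 and Scd1 were lower. Ldhb, Trh and Emp1 lie on chromosome 6, whose median was -0.24 in the peritoneal pair. None of these 12 passed the limma threshold over all genes, with Benjamini-Hochberg adjusted p from 0.114 for Spink3 to 0.814 for Mcts2 and Aqp3, all 12 having an unadjusted p under 0.05. In limma 11 of the 12 passed at a minimum of 5 FPKM and 11 without small RNA genes, all but Mcts2 each time, and 6 passed with robust moderation. The 12 had been picked from these same libraries for large ratios of the same sign in both pairs. Low p-values were therefore favoured by the choice and add no support. The authors' deposited tables called Cd109, Ldhb and Trh, beside Meg3, Mirg and Rian, lower in the 4N- line of both pairs, and no gene higher in both.

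The lists were also tested across both pairs with camera in limma at a preset correlation of 0.01. 2-cell-like genes were higher in the 4N- lines (Benjamini-Hochberg adjusted p = 2.23e-20, 14 of 15 genes higher in both pairs), as were the sex chromosome list (7.15e-06), p53 targets (3.24e-05), trophoblast genes (0.0157) and germline genes (0.0352), while fibroblast genes were lower (1.40e-07, 9 of 21 lower in both pairs). No list held with an estimated correlation (0 at unadjusted p under 0.05): limma gave adjusted p = 0.772 with an estimated correlation for 2-cell-like, sex chromosome, p53, trophoblast and germline genes and 0.854 for fibroblast genes. That alternative rests on the 1 residual degree of freedom and could hardly call any list, so it decides little. The sex chromosome list, whose estimated correlation was 0, still went from an unadjusted camera p of 1.26e-06 to 0.128. In limma germline genes also lost the call with no replicate block (adjusted p = 0.0980) and with no filter (0.157), and germline and trophoblast genes lost it at a minimum of 5 FPKM (0.164 and 0.113). The other 11 lists had camera adjusted p from 0.115 to 0.759 in limma. Among them, camera called mesoderm genes lower at a minimum of 5 FPKM (adjusted p = 0.00355, 3 genes) and higher with no filter (0.0228, 25 genes). With no filter camera also called extraembryonic endoderm (adjusted p = 0.0428) and neural ectoderm genes (0.0319) higher. DNA repair (0.0428) and histone and chromatin genes (0.0421) were called lower there. Both pairs were higher for 8 of 23 p53, 5 of 19 trophoblast, 8 of 20 germline and 2 of 4 sex chromosome genes. The p53 median lay outside the random lists in the peritoneal pair and not in the tail tip pair, and the trophoblast median in the tail tip pair and not in the peritoneal pair, a difference that was not tested. The sex chromosome result came from the tail tip pair and the fibroblast result largely from the 4N+ peritoneal line. Only 2 of 22 2-cell-like genes reached 1 FPKM in that line, against 13 in the 4N+ tail tip line. With 3 measured in the peritoneal pair, most of the 14 shared signs rest there on values under 1 FPKM.

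Adjusted over the list alone, limma called 8 of 15 2-cell-like genes higher (Zscan4c, Zscan4d, Zscan4e, Zscan4f, Tcstv1, Tcstv3, Dub1a and Arg2), against 0 over all genes (9 at unadjusted p under 0.05). With no replicate block, and with any library left out, 0 of the 15 were called. The fits with a library left out also have no block, so they set lines of different parental cells and separate scalings against each other. In them the log2 ratio of Zscan4d was 0.06 without the 4N+ peritoneal line and -0.15 without the 4N- tail tip line, and that of Tcstv3 -0.19 and -0.10. Such sign changes, and those of Peg3 below, cannot be told apart from differences between parental cells or scalings. Within the pairs, 14 of the 15 genes were higher in both 4N- lines. Only 3 members reached 1 FPKM in a peritoneal library, so most of these signs rest there on values near the floor. Several of the genes, such as Zscan4c, Zscan4d and Tcstv1, also have near-identical copies and are not separate agreements. In the imprinted list limma called 6 of 26 adjusted over the list alone, with Meg3, Rian and Mirg lower and Igf2, Peg3 and Mest higher, and 3 over all genes. With no replicate block, and with any library left out, the calls over the list alone were Meg3, Rian and Mirg, and the log2 ratio of Peg3 turned to -0.18 without the 4N+ tail tip line and -0.13 without the 4N- peritoneal line. Sct (trophoblast), Eif2s3y (sex chromosome) and Lefty2 (mesoderm, lower) were the only calls of their lists, and ended with no replicate block. The other 12 lists had 0 calls in limma, with 0 to 5 genes each at unadjusted p under 0.05, but 11 of 21 fibroblast genes were called without small RNA genes and 6 without the 4N+ tail tip line. No pluripotency gene was called (1 at unadjusted p under 0.05), 4 of 26 being higher and 6 lower in both pairs.

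The design sets H2A.X loss in ESC beside the 4N- state. No library is shared between the comparisons. Trophoblast genes, with a median of 2.10 in the knockout, had medians of 0.01 and 0.33 in the 4N- lines of the peritoneal and tail tip pairs. Between the knockout and the peritoneal pair, 12 genes were at least 2-fold higher in both and 16 lower in both, against 3.30 and 2.70 for independent lists over 11281 genes. Tcstv1 was among the first, and Dnmt3a, Enpp3 and Myc among the second. More genes, 38, differed 2-fold in opposite directions, against 6.46 for independent lists. Between the knockout and the tail tip pair 1 gene was higher and 11 lower in both, against 0.720 and 1.39, and 18 differed in opposite directions, against 2.62. Without small RNA genes these became 1 the same way and 4 opposite. Between the iPSC pairs 5 genes were higher and 10 lower in both, against 0.0541 and 0.239 for independent lists, and 12 differed in opposite directions, against 0.253. Without small RNA genes the 4 left the same way were Meg3, Rian, Mirg and Rangrf, and 0 were opposite.

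Across genes, which are not independent replicates, the log2 ratios of the knockout correlated with those of the peritoneal pair at Pearson r = 0.153 and Spearman rho = 0.263, and with those of the tail tip pair at r = 0.0188 and rho = 0.0699. The correlation between both iPSC pairs was r = -0.167 and rho = -0.0969, and r = 0.0299 without small RNA genes.

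Chromosome 17 stood apart in the peritoneal fibroblast pair, and was the only autosome to do so by the rule. Measured genes of chromosome 17 had a median of 0.37 above all autosomal genes in the 4N- line, with the other autosomes between -0.25 and 0.13. Chromosomes 11 and 6 had medians of -0.25 and -0.24 and chromosome 8 one of 0.13, none of them beyond the range of the other autosomes by more than their median absolute deviation. Each of chromosomes 11 and 6 widened the range for the other, and chromosome 17 for chromosome 8, so the rule could not flag them. Measured in that deviation, chromosomes 17, 11, 6 and 8 lay 16.8, 13.4, 13.2 and 6.04 from the other autosomes' median, and the remaining autosomes at most 4.83. Over genes at 5 FPKM or more in both libraries the medians were 0.38 (335 genes, 97.0% of them above 0), -0.27 (636 genes), -0.27 (326 genes) and 0.14 (440 genes). In the tail tip pair all autosomes lay between -0.03 and 0.03. In the ESC they lay between -0.21 (chromosome 13) and 0.10 (chromosome 7).

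**Figure D4:**
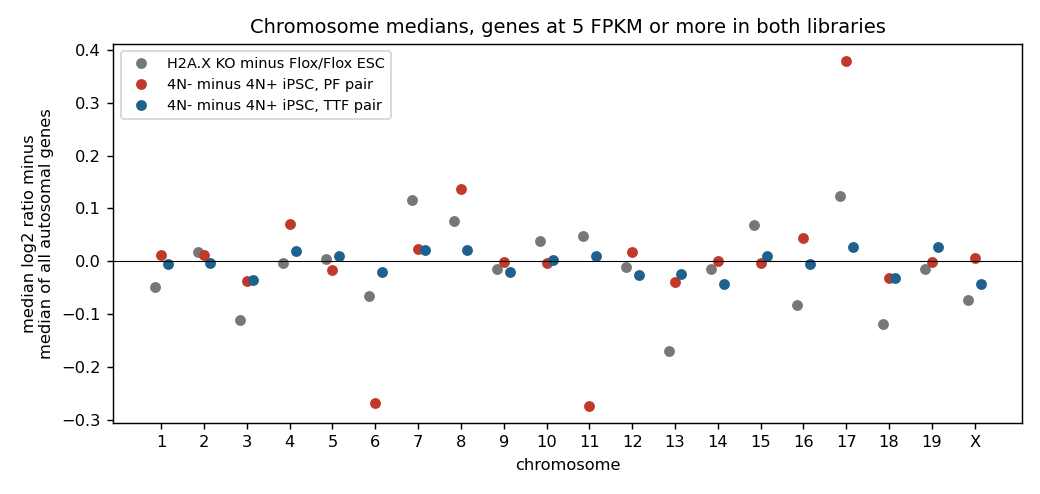
Points give, for each chromosome and comparison, the median log2 ratio of genes at 5 FPKM or more in both libraries minus the median of all autosomal genes, on the log2(FPKM + 1) scale. In the peritoneal fibroblast pair chromosome 17 lies at 0.38 and chromosomes 6 and 11 at -0.27.

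Some values carry limits of the quantification. Small RNA genes held 14.4% to 26.5% of summed FPKM. The housekeeping genes Gapdh (90 near-identical partners) and Ppia (20), named after their values were seen, stood below 1 FPKM in every library. Zscan4c and Zscan4d have 9 such partners each, and Meg3, Ldhb, Nanog, Cdkn1a, Cdkn1c, Tagln, S100a4, Csf1r, Arg2, Mest, Gbx2, Lefty2, Xist and Kdm5d have at least 1, so their values are uncertain to that extent. Xist overlaps Tsix on the other strand. Of 1407 olfactory and vomeronasal receptor genes, which pluripotent cells are not known to use, 167 were above 0 in the knockout ESC, 100 in the Flox/Flox ESC, 82 and 53 in the 4N- and 4N+ peritoneal lines, and 128 and 127 in the tail tip lines.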

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

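The comparison of both iPSC pairs in this part was chosen after the pairs had been seen and was not tested, because each pair has 1 library per label. Of 234 named genes, 5 differed at least 1.5-fold between 4N- and 4N+ lines in both pairs but in opposite directions. The imprinted gene Nnat was higher in the 4N- line of the peritoneal fibroblast pair (log2 1.88) and lower in that of the tail tip fibroblast pair (-0.86), a difference of 2.73. Grb10, also imprinted, showed ratios of 1.51 and -0.81, a difference of 2.32. In the other 3 genes the 4N- line was lower in the peritoneal and higher in the tail tip pair. Rhox6 had ratios of -1.24 and 0.64, a difference of -1.89, Myc had ratios of -1.13 and 0.73, a difference of -1.85, and Gbx2 had ratios of -0.97 and 0.69, a difference of -1.66. Grb10 lies on chromosome 11, whose median was -0.25 in the peritoneal pair, in the direction opposite to its own ratio.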

How the results depend on the processing

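Small RNA genes and chromosomes 6, 8, 11 and 17 were left out, and genes not marked OK in the authors' tables removed, and calls over each list alone repeated under each setting, only after the data had been seen; the other alternatives were planned. The cause of each change was not tested, unless the setting changes the number of genes or libraries by itself.

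Counts of 2-fold genes depended on the limit and the pseudocount. In the ESC the 1354 genes became 2221 with a pseudocount of 0.1, 4081 at 1.5-fold and 370 at 3-fold. In the peritoneal pair 180 became 312, 793 and 89, and 108 without small RNA genes. In the tail tip pair 85 became 197 at 1.5-fold and 18 without small RNA genes. The 15 genes shared by both pairs became 39 at 1.5-fold and 4 without small RNA genes, and each pair alone gave 85 or 180. Genes shared by the knockout and the peritoneal pair, 28, became 63 with a pseudocount of 0.1, 247 at 1.5-fold, 9 at 3-fold, 17 without small RNA genes and 18 without the 4 chromosomes. Those shared by the knockout and the tail tip pair, 12, became 20, 45, 7 and, without small RNA genes, 1.

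The calls of the iPSC fit moved widely. Against 14 calls in limma there were 0 with no expression filter (602 at unadjusted p under 0.05), 67 at a minimum of 5 FPKM, 37 with robust moderation, 9 without the 4 chromosomes and 93 without small RNA genes, where the prior spread was taken as common to all genes. With no replicate block limma called 3 genes, all small RNA genes. Leaving out each library in turn, without the block and with the lone library assumed to vary like the other group, gave 1 to 17 calls: 14 without the 4N+ peritoneal line, 3 without the 4N+ tail tip line, 1 without the 4N- peritoneal line and 17 without the 4N- tail tip line. Lines from the same parental cells deviated together from the mean of their label (correlation 0.441 over 11985 genes), which with 2 pairs is only a hint. Such lines also share a scaling, so parental cells and scaling cannot be told apart here. Over all settings the log2 ratio stayed between -5.69 and -3.84 for Meg3, with limma's Benjamini-Hochberg adjusted p from 2.04e-155 without small RNA genes to 0.999 with robust moderation. List tests, 6 calls, became 10 with no filter, without germline genes, and 0 with an estimated correlation or fry, both with 0 at unadjusted p under 0.05 (limma's adjusted p from 0.772 to 0.902 in fry). Both of these rest on the 1 residual degree of freedom and could hardly call any list.

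The trophoblast median of 2.10 in the ESC was 2.90 and 2.28 with pseudocounts of 0.1 and 0.5, 1.74 with no filter, 3.88 at a minimum of 5 FPKM and 2.30 after centring. The pluripotency median there became -0.64 after centring. The 2-cell-like median of the tail tip pair became 0.81, 0.67, 0.40 and 0.65 under the first 4 of these, and the fibroblast median of the peritoneal pair became -1.04 and -0.88 with the pseudocounts, -0.61 at 5 FPKM and -0.53 after centring. At a minimum of 5 FPKM 8 lists lay outside the random lists in the peritoneal pair and 2 in the tail tip pair, against 5 each. Among lists outside the random lists, direction reversed for the fibroblast list of the tail tip pair (0.0117 with no filter, 0.0193 at 5 FPKM), the extraembryonic endoderm list of that pair (-0.0870 at 5 FPKM) and the pluripotency list of the peritoneal pair (0.0901 after centring).

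Correlations across genes became 0.205 (ESC and peritoneal pair), 0.0865 (ESC and tail tip pair) and 0.0299 (both pairs) without small RNA genes, and 0.0741 for the ESC and the tail tip pair without the 4 chromosomes. Medians in the peritoneal pair kept their sign: with pseudocounts of 0.1 and 0.5, no filter, a minimum of 5 FPKM and 5 FPKM in both libraries they were 0.42, 0.39, 0.19, 0.41 and 0.38 for chromosome 17, -0.27, -0.26, -0.12, -0.27 and -0.27 for chromosome 6, -0.28, -0.26, -0.21, -0.27 and -0.27 for chromosome 11, and 0.14, 0.14, 0.0464, 0.14 and 0.14 for chromosome 8. Over genes at 5 FPKM in both libraries 1 autosome of the ESC (chromosome 13, at -0.17), in place of 0, lay beyond the range of the others by more than their median absolute deviation. Another 96 values of these results and 155 other list medians moved less than the limits set for them, and 61 moved by more. Of these 61, all but 50 changed sign, in lists that lay within the random lists in the main analysis. With no filter they were extraembryonic endoderm (-0.05), neural ectoderm (0.07, then outside at percentile 99.1) and mesoderm (0.01) of the peritoneal pair and mesoderm (0.04) of the tail tip pair. At 5 FPKM they were neural ectoderm (-1.17, then outside at percentile 0) and mesoderm (-0.13) of the ESC and germline (-0.05) and stress genes (-0.04) of the tail tip pair. After centring they were imprinted (0.10) and DNA repair genes (0.01) of the peritoneal pair and reference genes (0.03) of the ESC. Of the 155, 7 medians of the tail tip pair near 0 also changed sign. Tests on counts (edgeR and DESeq2) were not run, since no table holds counts. Leaving out genes of several lists moves nothing, as there are none. Depth limits genes under 1 FPKM, and with 1 library per condition depth cannot stand in for replicates.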

Other observations

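In this part, the test of chromosome copy number by expression level was set down before its result was seen, and the other tests and the interferon list were chosen after it. Interferon response genes, a group outside the 17 lists, were higher in the H2A.X knockout ESC: 9 of 21 measured genes were at least 2-fold higher, and the median of 0.98 lay above all matched random lists. The ubiquitin-like modifier gene Isg15 stood at 14.8 against 0.254 FPKM, the chemokine gene Cxcl10 at 17.3 against 0.630 FPKM, Usp18 at 5.77 against 0.154 FPKM and Rsad2 at 3.87 against 0.202 FPKM. In the iPSC the medians were -0.30 for the peritoneal pair (percentile 0.745, -0.14 after centring) and -0.01 for the tail tip pair (percentile 54.4). Of the 28 interferon members, 11 reached 1 FPKM in the Flox/Flox ESC, so the others measured in the ESC entered through the knockout. As the list was chosen after the data had been seen, its place among random lists is a description and adds no support.

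The lower Meg3, Rian and Mirg of 4N- iPSC were weighed first. A lost segment of chromosome 12 reaching the flanking genes was argued against by genes within 2 Mb on both sides, whose median log2 ratio was -0.18 over 27 genes in the peritoneal pair and -0.00463 over 25 genes in the tail tip pair. A general 2-fold change of imprinted genes was argued against, since 0 of the 22 others measured in both pairs differed 2-fold the same way in both, but smaller changes stay open, as Igf2, Peg3 and Mest were higher in limma adjusted over the list alone, though not with no replicate block. A narrower deletion stays open, as does silencing of the maternal cluster, which is a hypothesis that expression alone cannot separate from it. The label 4N-, the biological difference that the design names, was shared by the 2 lines with low values and could account for them, but both ESC libraries were also low for Meg3, at 0.251 and 0.202 FPKM against 0.188 and 1.52 FPKM in the 4N- lines.

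The chromosome shifts between the peritoneal fibroblast lines were weighed next, with chromosomes 6, 8 and 11 singled out after their medians were seen, since by the rule only chromosome 17 stood apart. Bias from GC content or transcript length was argued against: after medians of GC and length classes were removed, chromosome 17 stayed at 0.37. A difference in copy number, in part or all of the cells, is a candidate explanation, since in all 12 expression classes (3 on each of chromosomes 6, 8, 11 and 17) the median had its chromosome's sign and at least 0.560 times its size. Along each of these chromosomes every 20 Mb block also had the same sign, from 0.32 to 0.40 on chromosome 17. Against the other tables, a comparison across separate scalings, the 4N+ line stood at 0.25 on chromosomes 6 and 11 and -0.35 on chromosome 17, and both lines were higher on chromosome 8, at 0.41 (4N-) and 0.28 (4N+).

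The higher trophoblast and lower pluripotency expression of the knockout ESC was weighed last. A smaller share of stem cells, lowering every pluripotency gene alike, was not decided by its test. The median absolute deviation of the members' log2 ratios, 0.271, lay at percentile 13.1 of matched random lists, which decides neither way. That deviation does not register single members at the extremes. In these 2 libraries the members did not all fall alike. Among the 26 measured, 1 was higher and 25 lower, 8 of them at least 2-fold, while Nanog was level. A single scaling factor moves all lists alike, so by itself it would not place the pluripotency median of -0.84 below the matched random lists (-0.53 to -0.02). That place had already marked the pattern before this check was set down, so the check was fixed in advance and adds no separate evidence. Feeder fibroblasts as the source of the fibroblast genes were argued against by the highest of Col1a1, Col1a2 and Col3a1 at 0.291 FPKM in the knockout, and 9 of the 27 members of that list reached 1 FPKM in the Flox/Flox ESC. Loss of H2A.X, the difference the design names, and a difference between single cultures in how far cells had differentiated both stay open, because each condition had 1 library.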
